A study of Mus musculus with 18 samples.

How the data were processed

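Kidney cortex from 18 mice was profiled by RNA sequencing, with 3 mice in each of 6 groups. The healthy controls were MRL/MpJ wild type mice given vehicle. The other 15 mice were MRL/lpr, a strain in which a mutated Fas gene leads to lymphoproliferation and a lupus-like kidney disease, and received vehicle, MMF, FK506, prednisone or the multi-target treatment. Mycophenolate mofetil (MMF) blocks inosine monophosphate dehydrogenase in purine synthesis, FK506 (tacrolimus) inhibits calcineurin, and prednisone activates the glucocorticoid receptor. The labels give no doses, and do not say which drugs made up the multi-target treatment. Per the labels, the tissue was frozen, RNA was purified on columns, and libraries were made from 1 ug of total RNA. Mouse numbers in the sample titles serve as replicate names and pair no samples across groups.

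The deposited values are log2 expression values per gene symbol, for 15035 genes in the same order in every library. The submitters' processing notes name limma and the mm10 build, without versions or roles, and the aligner and annotation are not given in the sources used here. From the values, 2 to the power of a deposited value is a whole number of reads times 1 factor per library, within 0.001 reads, for 75.0% to 75.4% of genes. For 11164 genes this held in at least 17 libraries. The other genes were not whole on that scale, and how they were summarised is unknown. No value was missing, and the lowest value of each library stood for at least 1 read, so genes without reads in some library may have been left out or replaced before deposit. In 23 rows a spreadsheet had turned the gene name into a date, and these rows were tested but are not named.

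Expressed in recovered reads, the gene values summed to between 28939845 reads (MMF mouse 27) and 41066953 reads (prednisone mouse 23) per library. The factor of each library gave relative depths from 67.1% to 100% of the deepest one. The median gene stood at 810 reads, and 0.151% of values were under 10 reads, so the spread between mice limits the precision of most genes more than counting error does. The within-group SD of the median gene was 0.22 on the log2 scale.

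The log2 values were fitted as deposited, with no filter and no pseudocount, in a limma (version 3.58.1, R 4.3.3) model of group means over all 18 libraries, with 12 residual degrees of freedom and a mean-dependent prior variance. In all, 13 comparisons were tested, each with Benjamini-Hochberg adjustment over the 15035 genes at 0.05. They were disease (vehicle against healthy), each of 4 drug arms against vehicle, the multi-target arm against each single drug and against the sum of the 3 single-drug effects, and each treated arm against healthy. The 35 gene lists covered immune cells, interferon and antigen presentation, nephron segments, injury, metabolism, drug-related pathways and tissues next to the kidney. Each was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusting over the 35 lists within a comparison. A preset-correlation camera test treats the members of a list as nearly independent, whereas the estimated correlation uses how the members vary together between mice.

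Most genes named in the text follow a fixed rule. In each comparison it takes the 5 largest rises and 5 largest falls among called genes with non-overlapping groups and a symbol other than a numbered gene model. It adds up to 3 members with the smallest p from each of at most 8 lists called by camera, and check genes: Fas for disease, Impdh1 and Impdh2 for MMF, Rcan1 for FK506, Fkbp5 and Tsc22d3 for prednisone, and all 6 for the multi-target arm. For drugs it also follows the 3 largest disease changes in each direction. A result on a further selected gene is not reported here. Chosen outside the rule, after their values were seen, were Adipoq, Cyp11a1, Cfd, Upk1b and Hsd3b1 for other tissues, Ezh1, Slc22a26, Cp and Sult2a4 for the genes alike in all MRL/lpr groups, Fkbp5 for MMF, and Kap where it did not pass. Non-overlap of 3 against 3 mice occurs by chance in 10% of genes. The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

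A reversal slope measured movement along the disease difference. It is the slope across genes of the drug-minus-vehicle difference on the vehicle-minus-healthy difference. An estimate of the covariance and variance that the shared vehicle libraries contribute was removed. That estimate came from residual variance pooled over all 6 groups, so too little is removed where vehicle mice vary more than the others. A slope of 0 is no movement and -1 a full return to the healthy level. Unchanged groups were simulated 100 times by giving every MRL/lpr group the vehicle mean and drawing whole-library residuals. For these groups the residuals were drawn from all 15 MRL/lpr libraries together.

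The gene calls, list calls and reversal slope were tested on simulated data first. With 200 changed genes among 15035 in MMF against vehicle, the model called 26% of genes changed by 0.5 on the log2 scale, 70% at 1, 92% at 2 and 100% at 3, with 9 false calls among 153. In vehicle against healthy it called 12%, 84%, 98% and 100%, with 10 false calls among 157. Of 5 lists shifted by 0.5, all 5 were called by each method, and preset-correlation camera also called 1 of 27 unshifted lists. A true slope of -0.5 was returned as -0.503 and a slope of 0 as -0.001. These simulations drew genes independently, which real libraries do not.

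Alternatives left out the lowest 25% of genes, the trend of the prior variance, or all groups outside the comparison, used quantile normalization or array weights, or left out each library in turn. The last 2 were added after the data had been seen: voom on whole-read genes, and leaving out both libraries that held transcripts of neighbouring tissues. The planned pseudocount and negative binomial alternatives, meant for linear values or raw counts, were not run on these log2 values. Gene locations are from GENCODE release M 21 on GRCm38 (mm10). Figures were drawn with matplotlib 3.10.9.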

Results

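The series measured kidney cortex transcriptomes of healthy, vehicle-treated and drug-treated lupus nephritis mice, and its title names combination therapy as the subject. There were 6 groups of 3 mice: MRL/MpJ healthy controls and MRL/lpr mice on vehicle, MMF, FK506, prednisone or the multi-target treatment. Libraries held between 28939845 (MMF mouse 27) and 41066953 (prednisone mouse 23) recovered reads over 15035 genes. The first principal component carried 41.1% of the variance and the second 28.8%. Healthy mice lay at -53.4, -48.9 and -43.9 on the first, and vehicle mice at 17.2 (mouse 7), 34.7 (mouse 17) and 79.3 (mouse 36). Some pieces of tissue held other transcripts. Adipoq, an adipocyte hormone, was at 11.3 in vehicle mouse 17 against 3.89 and 4.07 in vehicle mice 7 and 36. Cyp11a1, an enzyme of steroid synthesis in the adrenal gland, was at 11.37 in FK506 mouse 12 against 5.49 and 5.73 in FK506 mice 3 and 24.

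**Figure D1:**
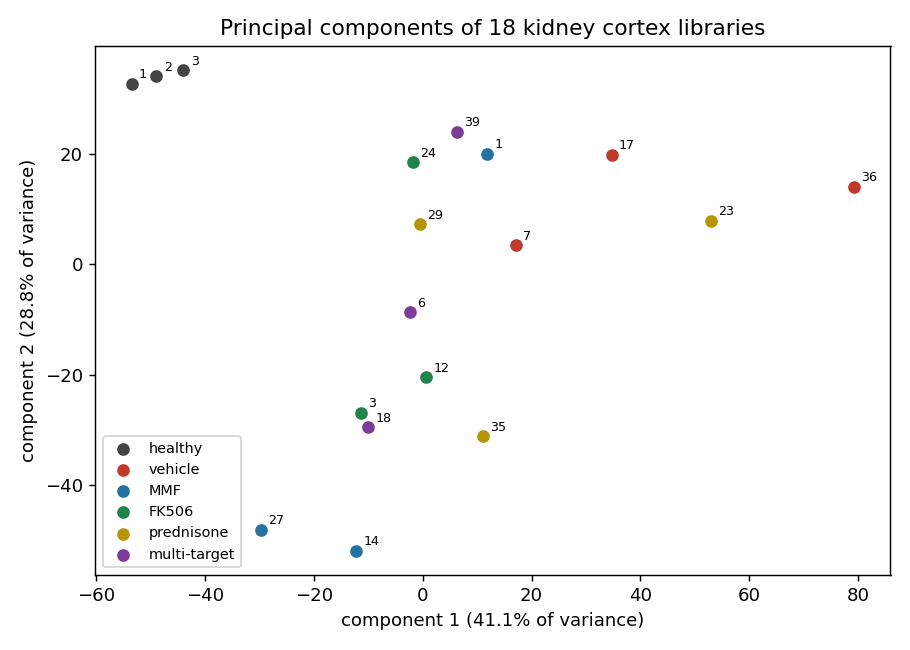
Principal components of the 18 libraries, with component 1 (41.1% of variance) on the x axis and component 2 (28.8%) on the y axis; each point is a mouse, coloured by group and marked with its number. The 3 healthy mice sit together at the left, and vehicle mouse 36 is farthest to the right at 79.3.

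Diseased kidneys were compared with healthy ones to describe the disease. Genes of immune infiltration and interferon response rose in vehicle-treated MRL/lpr mice. The 5 largest rises were Ubd, a ubiquitin-like protein induced by interferon (log2 difference 7.16 ± 1.06 SE, limma adjusted p = 0.000352), Saa3, an acute-phase protein (7.16 ± 0.52), Fpr2, a formyl peptide receptor of myeloid cells (6.96 ± 0.53), and the interferon-inducible GTPases Iigp1 (6.87 ± 0.69) and Tgtp1 (6.68 ± 0.63), with n = 3 mice per group. The 5 largest falls were Dnase1, a secreted nuclease (-3.73 ± 0.81, limma adjusted p = 0.00515), the carboxylesterases Ces1d (-3.29 ± 0.39) and Ces1e (-2.81 ± 0.35), the prolactin receptor Prlr (-3.19 ± 0.76) and the histidine decarboxylase gene Hdc (-2.55 ± 0.56). On GRCm38, Ubd lies on chromosome 17 from 37193892 to 37196095 and Dnase1 on chromosome 16 from 4036942 to 4040024, both protein-coding.

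All 17 measured members of the MHC and antigen presentation list rose, both over all genes and adjusted over the list alone, among them H2-DMb1 (4.26), H2-D1 (3.94) and the immunoproteasome subunit Psmb8 (5.23). Macrophage and myeloid markers rose in 21 of 22 members (22 adjusted over the list alone), with Ctss at 4.74, C1qa at 4.18 and Fcgr3 at 3.48. Type I interferon-stimulated genes rose in 22 of 25 (24 adjusted over the list alone), including Ifih1 (1.90), Stat2 (1.60) and Bst2 (3.59). T cell markers rose in 15 of 17 (16 adjusted over the list alone), with Cd4 at 3.01, Pdcd1 at 4.32 and Lck at 2.89. Complement genes rose in 12 of 15 (14 adjusted over the list alone), including C4b (4.44) and C3ar1 (3.88). These 5 lists were called by camera with the preset correlation; with an estimated correlation their adjusted p was 0.261, 0.263, 0.319, 0.293 and 0.261 in the same order. Lymphoid organ stroma markers, from tissue that also holds T cells, rose in 2 of 6 members (3 adjusted over the list alone), with list means of 0.79, 1.43 and 2.56 above healthy in vehicle mice 7, 17 and 36. Camera called that list (median 1.17, adjusted p = 0.032); adjusted p = 0.319 with an estimated correlation. The call ended without vehicle mouse 36 (median 0.53, 0.109), with only the 2 groups fitted (0.0775) and under quantile normalization (0.0547).

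Some members of 2 metabolic lists and of the proximal tubule list fell. Of 39 oxidative phosphorylation genes 17 fell (25 adjusted over the list alone), among them Ndufa10 (-0.64) and Uqcrc2 (-0.79); adjusted p = 0.319 with an estimated correlation. Fatty acid oxidation genes fell in 11 of 24 (19 adjusted over the list alone), with Ehhadh at -1.37, Acaa1b at -1.88 and Cyp4a10 at -1.26; adjusted p = 0.249 with an estimated correlation. Proximal tubule markers fell in 9 of 24 (12 adjusted over the list alone), with Cyp4b1 at -1.43, Slc4a4 at -0.98 and G6pc at -1.64; adjusted p = 0.263 with an estimated correlation. Slc4a4 lost its call under quantile normalization (adjusted p = 0.0548) and G6pc without vehicle mouse 36 (0.0561). Uqcrc2 lost it when only the 2 groups were fitted (0.059). Without vehicle mouse 36 the median of the oxidative phosphorylation list went from -0.44 to -0.255 and that of the proximal tubule list from -1.09 to -0.71. Loop of Henle and distal tubule markers fell in 2 of 16 (2 adjusted over the list alone) and were called downward (median -0.30, adjusted p = 0.00434); adjusted p = 0.367 with an estimated correlation. That call ended under quantile normalization (0.261) and without vehicle mouse 36 (median -0.026, 0.133), and the median was -0.52 without vehicle mouse 17.

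Further immune and injury lists were also called by camera. Chemokines and cytokines rose in 14 of 20 members (16 adjusted over the list alone), natural killer and cytotoxic markers in 7 of 7 (7 adjusted over the list alone), tubular injury markers in 11 of 21 (15 adjusted over the list alone) and extracellular matrix genes in 9 of 25 (14 adjusted over the list alone). With an estimated correlation their adjusted p was 0.316, 0.31, 0.396 and 0.435. Without vehicle mouse 36 the median of the injury list was 1.007 in place of 1.71, and that of the matrix list 0.76 in place of 1.33. Podocyte markers were not called by camera (adjusted p = 0.287), with 5 of 22 higher and 1 lower. Adipocyte and urothelial markers were not called either (adjusted p = 0.255 and 0.205), and their medians of 2.01 and 1.54 include vehicle mouse 17. Fas was higher by 1.34 ± 0.15 (limma adjusted p = 3.81e-05). The lpr mutation is an insertion in an intron, so the summed Fas value does not check the genotype label.

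In all, 3369 genes changed in disease, 2353 higher and 1016 lower, and 5599 had an unadjusted p under the threshold. Camera called 24 of 35 lists with the preset correlation, 0 with an estimated correlation, and fry called 23. The median of all genes was 0.09 higher in vehicle mice, and quantile normalization turned the split of called genes from 69.8% higher to 43.7%. Of all genes, 52.4% had non-overlapping groups, where chance gives 10%. The count was 2226 without the lowest 25% of genes, 5519 with array weights, 1490 without vehicle mouse 36, and 1744, 1824 and 1863 without healthy mice 1, 2 and 3. Without the lowest 25% fewer genes were tested, and lists left with under 5 members were dropped. Camera called 15 lists there.

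**Figure D2:**
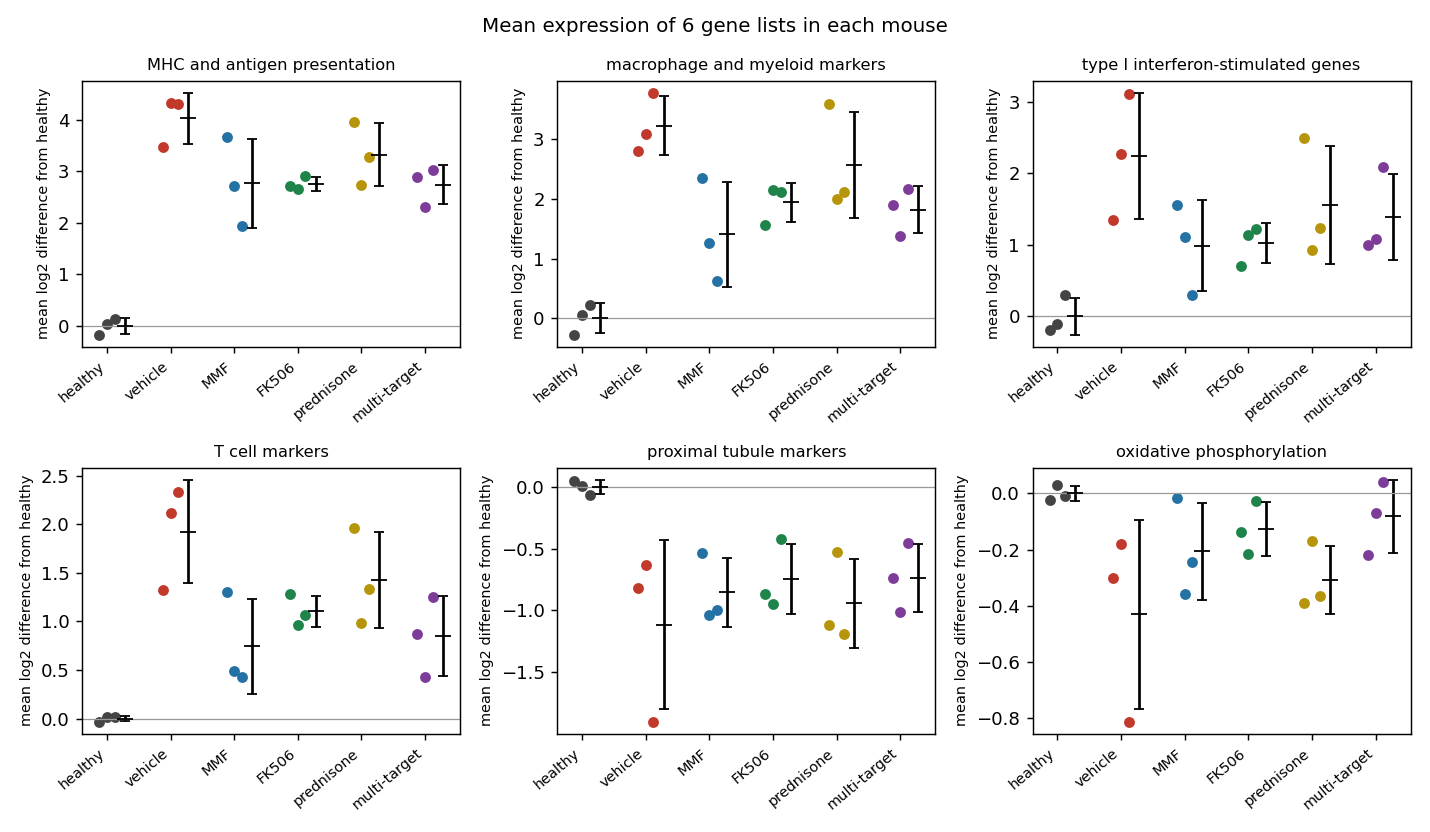
Mean log2 difference from the healthy group over the members of 6 gene lists (y axis) in each of 18 mice (points) of 6 groups (x axis), with bars for the group mean and SD, n = 3. Vehicle mice averaged 4.03 for antigen presentation and -0.43 for oxidative phosphorylation.

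MMF was compared with vehicle to describe its effect within diseased mice. The largest rises were the fatty acid hydroxylases Cyp4a14 (2.23 ± 0.39 SE) and Cyp4a10 (1.47 ± 0.27), the gluconeogenic enzymes G6pc (2.19 ± 0.40) and Pck1 (2.15 ± 0.47), and Ces1e (1.47 ± 0.35). The largest falls were Saa3 (-2.75 ± 0.52), the B cell and myeloid receptor Cd180 (-2.47 ± 0.58), the lectin Clec4a3 (-2.43 ± 0.56), the chemokine Ccl4 (-2.31 ± 0.55) and Ciita, the master regulator of MHC class II genes (-2.19 ± 0.45). Macrophage markers fell in 4 of 22 members (22 adjusted over the list alone), including Mrc1 (-1.13), Fcgr3 (-1.73) and Cd68 (-2.01); adjusted p = 0.555 with an estimated correlation. T cell markers fell in 1 of 17 members, Lck at -1.81 (16 adjusted over the list alone), and antigen presentation genes in 1 of 17, Ciita (17 adjusted over the list alone); adjusted p = 0.555 with an estimated correlation for each. The antigen presentation median of -1.23 was -0.78 without MMF mouse 27. Lymphoid organ stroma markers had a median of -1.09 and were not called (adjusted p = 0.221).

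No oxidative phosphorylation gene passed the test with MMF over all genes (0 adjusted over the list alone), though 36 of 39 estimates were above 0 and camera called the list upward; adjusted p = 0.555 with an estimated correlation. That call ended without vehicle mouse 36 (adjusted p = 0.0526) or MMF mouse 1 (0.0597), and the median of 0.24 was 0.03 and 0.135 without them and 0.37 without vehicle mouse 17. Proximal tubule and loop of Henle markers were also called by camera. Their means against healthy were -1.12 and -0.49 in vehicle and -0.855 and -0.17 in MMF mice. Both calls ended without vehicle mouse 36 (adjusted p = 0.527 and 0.923) or MMF mouse 1 (0.361 and 0.149) and under quantile normalization (0.351 and 0.345). Fatty acid oxidation genes rose in 2 of 24 (5 adjusted over the list alone), and the estimated-correlation p was again 0.555; their median of 0.39 was 0.61 without vehicle mouse 17 and 0.24 without MMF mouse 1. Extracellular matrix genes had 0 of 25 members past the threshold (17 lower adjusted over the list alone), with Tgfb1 at -1.63, and cell cycle genes 0 of 28 (0 adjusted over the list alone); both were called downward by camera, with adjusted p = 0.555 with an estimated correlation. Without vehicle mouse 36 their medians were -0.68 in place of -1.33 and -0.47 in place of -0.89. Glucocorticoid-induced genes were above 0 in 16 of 21 members (median 0.66; 0 adjusted over the list alone), with Fkbp5 at 1.34 ± 0.48 (limma adjusted p = 0.0966), and camera called the list upward (adjusted p = 0.00152); adjusted p = 0.555 with an estimated correlation. That call ended under quantile normalization (0.0544) and without MMF mouse 14 (0.0979), and the median was 0.39 without vehicle mouse 7, 1.15 without MMF mouse 1 and 0.09 without MMF mouse 14. The drug targets Impdh1 (-0.38 ± 0.18, limma adjusted p = 0.171) and Impdh2 (0.05 ± 0.17, limma adjusted p = 0.86) did not pass. Of the other genes largest in disease, Ubd stood at -3.19 (limma adjusted p = 0.0834), Fpr2 at -1.99 (0.0572), Dnase1 at 1.86 (0.143), Ces1d at 1.18 (0.0838) and Prlr at -0.996 (0.379).

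MMF changed 238 genes, 20 higher and 218 lower, with a smallest limma adjusted p of 0.0429, and 4491 genes were under the threshold unadjusted. Camera called 18 lists and fry 4. The count was 0 when only the 2 groups were fitted, under quantile normalization, with voom, without both libraries with other-tissue transcripts, and without vehicle mouse 17, vehicle mouse 36, MMF mouse 14 or MMF mouse 27. It was 6753 with array weights, 28 without the lowest 25% of genes, 1933 without vehicle mouse 7 and 5538 without MMF mouse 1.

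FK506 was compared with vehicle in the same way, and no gene passed the limma test. All 17 antigen presentation members were below 0 (17 lower adjusted over the list alone), with Nlrc5 at -1.23 and Ciita at -1.63, as were all 22 macrophage markers (21 lower adjusted over the list alone), with Mrc1 at -0.98 and Cd68 at -1.53. The extracellular matrix list had 25 of 25 members below 0 (20 lower adjusted over the list alone), with Col1a2 at -2.18 and Col3a1 at -2.97. Camera called these 3 lists downward; adjusted p = 0.371 with an estimated correlation for each. The matrix median of -1.30 was -0.715 without vehicle mouse 36. Complement genes C1ra (-1.42) and C2 (-0.82) belonged to a list with 10 of 15 members lower adjusted over the list alone; adjusted p = 0.371 with an estimated correlation. All 39 oxidative phosphorylation genes were above 0 (0 adjusted over the list alone), with Ndufb9 at 0.54; adjusted p = 0.381 with an estimated correlation. Their median of 0.32 was 0.11 without vehicle mouse 36. Tubule marker lists moved the same way. Their means against healthy were -0.49 in vehicle and 0.09 in FK506 mice for loop of Henle, -1.12 and -0.75 for proximal tubule, and 0.12 and 0.48 for collecting duct. The proximal tubule call by camera ended without vehicle mouse 36 (adjusted p = 0.543) or FK506 mouse 24 (0.0923) and under quantile normalization (0.0853). The collecting duct call ended without FK506 mouse 24 (0.07). Calcineurin and NFAT target genes, the pathway FK506 inhibits, had 10 of 10 members below 0 (0 adjusted over the list alone) and were called by camera (median -0.46, and -0.71 without FK506 mouse 12; adjusted p = 0.00315); adjusted p = 0.371 with an estimated correlation. The list was also called downward for MMF (median -0.48, adjusted p = 0.0204), prednisone (-0.40, 0.00166) and multi-target (-0.61, 0.000146), with adjusted p = 0.555, 0.359 and 0.329 with an estimated correlation. The MMF call ended without the lowest 25% of genes (0.0981), vehicle mouse 36 (0.105) or MMF mouse 1 (0.0515), and the prednisone call without vehicle mouse 36 (0.106); the prednisone median was -0.63 without vehicle mouse 7, -0.07 without mouse 36 and -0.235 without prednisone mouse 29. T cell markers were below 0 in 17 of 17 with FK506 (median -0.85; 11 lower adjusted over the list alone) and were called downward; adjusted p = 0.381 with an estimated correlation. Lymphoid organ stroma markers had a median of -0.48 and were not called (adjusted p = 0.28). Immediate early and heat shock genes, which also respond to tissue handling, were below 0 in 13 of 14 with FK506 (0 adjusted over the list alone) and were called downward for FK506 (median -0.86, adjusted p = 0.0148), prednisone (-0.69, 0.00125) and multi-target (-0.64, 0.0191), with adjusted p = 0.467, 0.394 and 0.44 with an estimated correlation. Those calls ended without vehicle mouse 36 (medians -0.545, -0.11 and -0.43; 0.0914, 0.164 and 0.118), and the FK506 call also without FK506 mouse 3 (-0.53, 0.0934). The FK506 median was -0.54 without vehicle mouse 17, the prednisone median -0.28 without prednisone mouse 29, and the multi-target median -0.975 without vehicle mouse 7 and -0.97 without multi-target mouse 39. Rcan1, a reporter of calcineurin activity, stood at -1.05 ± 0.35 (limma adjusted p = 0.171). Adrenal markers were called upward, with a median of 1.66, and FK506 mouse 12 held the adrenal transcripts; adjusted p = 0.381 with an estimated correlation, and 0.442 by camera without that mouse.

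The limma count for FK506 was 0, with 2987 genes under the threshold unadjusted and 0 calls by voom. Camera called 21 lists and fry 0. The genes largest in disease stood at -3.39 (Ubd), -1.18 (Saa3), -0.95 (Fpr2), 2.02 (Dnase1), 1.23 (Ces1d) and 0.17 (Prlr). Leaving out vehicle mouse 7 gave 1 gene, and array weights gave 2326.

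With prednisone no gene passed the limma test, and several immune lists lay below vehicle. T cell, natural killer, chemokine and complement means above healthy were 1.43, 1.76, 2.05 and 2.12, against 1.93, 2.39, 2.73 and 2.60 in vehicle mice. The natural killer and chemokine calls by camera ended without vehicle mouse 36 (adjusted p = 0.102 and 0.171). The natural killer call also ended without prednisone mouse 29 (0.0935). The antigen presentation list had a median of -0.71, interferon-stimulated genes -0.71 and macrophage markers -0.69, with every member of the 3 lists below 0 and 0 past the threshold over all genes or adjusted over the list alone. Named members were Ciita (-1.07), Ifi27l2a (-0.99) and Mrc1 (-0.40). Camera called all 3; adjusted p = 0.359 with an estimated correlation for each. Without vehicle mouse 36 the interferon median was -0.19 and the macrophage median -0.38. Without prednisone mouse 29 the 3 medians were -0.38, -0.355 and -0.33. The interferon median was -1.29 without vehicle mouse 7 and -1.25 without prednisone mouse 23, and the macrophage median -1.22 without mouse 23 and -0.45 without mouse 35. Glucocorticoid-induced genes were above 0 in 18 of 21 members (0 adjusted over the list alone), and camera called the list upward (median 0.29, adjusted p = 0.01), as it did for MMF (median 0.66); adjusted p = 0.536 with an estimated correlation. The call ended without vehicle mouse 7 (0.0625), prednisone mouse 23 (0.0682) or prednisone mouse 35 (median 0.125, 0.255), and the median was 0.63 without vehicle mouse 36 and 0.555 without prednisone mouse 29. Glucocorticoid receptor targets stood at 1.16 ± 0.48 for Fkbp5 and 0.40 ± 0.33 for Tsc22d3, each with a limma adjusted p of 0.943. The genes largest in disease stood at -1.24 (Ubd), -0.12 (Saa3), -0.11 (Fpr2), 0.97 (Dnase1), 0.87 (Ces1d) and -0.765 (Prlr), none past the threshold. Adipocyte and urothelial markers were called downward (medians -1.15 and -0.56; adjusted p = 0.359 and 0.527 with an estimated correlation). Without vehicle mouse 17 their direction turned, with medians of 0.24 and 0.72, and camera called the urothelial list upward (adjusted p = 0.0446). The adipocyte call ended without prednisone mouse 23 (0.0535), and the urothelial call without mouse 23 (0.18) or mouse 35 (0.182) and with only the 2 groups fitted (0.0844).

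The limma count for prednisone was 0, with 474 genes under the threshold unadjusted and 0 by voom. Camera called 23 lists and fry 0. The oxidative phosphorylation list was called upward with a median of 0.13 (adjusted p = 0.626 with an estimated correlation). Without vehicle mouse 36 camera called 15 lists and called this one downward (median -0.06, adjusted p = 0.000184), and without prednisone mouse 29 it was not called (0.526).

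The multi-target arm against vehicle was compared in the same way, and no gene passed the limma test. Macrophage markers were below 0 in 22 of 22 members (21 lower adjusted over the list alone), with Itgam at -1.31 and Cd68 at -1.64. Antigen presentation genes were below 0 in 17 of 17 (17 lower adjusted over the list alone), with Tap1 at -1.31, and T cell markers in 17 of 17 (15 lower adjusted over the list alone), with Cd3g at -1.57 and Thy1 at -2.09. Oxidative phosphorylation genes were above 0 in 39 of 39 members (16 higher adjusted over the list alone), with Cox4i1 at 0.49 and Ndufb8 at 0.51, and their median of 0.35 was 0.16 without vehicle mouse 36. Camera called all 4 lists; adjusted p = 0.329 with an estimated correlation for each. Lymphoid organ stroma markers had a median of -0.64 and were not called (adjusted p = 0.0967). Tubule marker lists moved with oxidative phosphorylation. Their means against healthy were -0.49 in vehicle and 0.08 in multi-target mice for loop of Henle, and -1.12 and -0.74 for proximal tubule. The proximal tubule call by camera ended without vehicle mouse 36 (adjusted p = 0.205). The genes largest in disease stood at -3.20 (Ubd), -0.79 (Saa3), -1.31 (Fpr2), 1.47 (Dnase1), 0.76 (Ces1d) and -0.05 (Prlr). The cytokine Il1b stood at -1.69 ± 0.39 (limma adjusted p = 0.163). The check genes were Impdh1 at -0.24, Impdh2 at 0.01, Rcan1 at -0.51, Fkbp5 at 0.87, Tsc22d3 at 0.01 and Fas at -0.10, none of which passed.

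The limma count was 0, with 2341 genes under the threshold unadjusted and 0 by voom. Camera called 21 lists and fry 0. The count was 38 without vehicle mouse 7 and 2785 with array weights. Adipocyte and urothelial markers were called downward (medians -2.03 and -1.12; adjusted p = 0.44 and 0.434 with an estimated correlation), and without vehicle mouse 17 their medians were 0.18 and -0.05 with neither called (adjusted p = 0.709 and 0.824). Without multi-target mouse 39 they were not called either (0.0573 and 0.102), nor with only the 2 groups fitted (0.12 and 0.0928).

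The multi-target arm was next compared with each single drug, to ask whether the combination differed from its counterparts. Against MMF, glucocorticoid-induced genes were lower by camera (median -0.49), with Errfi1 at -0.81 and Zbtb16 at -1.35, and podocyte markers higher (median 0.17), with Nphs1 at 0.46; adjusted p = 0.966 with an estimated correlation for both. Against FK506, podocyte markers were higher (Nphs1 at 0.48; adjusted p = 0.134 with an estimated correlation), interferon-stimulated genes higher (median 0.36; adjusted p = 0.964 with an estimated correlation) and adrenal markers lower (median -1.65; adjusted p = 0.369 with an estimated correlation). Against prednisone, oxidative phosphorylation genes were above 0 in 39 of 39 (median 0.22), and macrophage markers (median -0.74) and T cell markers (median -0.55) below 0 in every member; adjusted p = 0.591 with an estimated correlation for each of the 3. No member of these lists passed over all genes or adjusted over the list alone. Limma called 0 genes in each of the 3 comparisons, with 1126, 61 and 503 under the threshold unadjusted and 0 by voom. Without MMF mouse 1 the count against MMF was 2521. The glucocorticoid call against MMF ended without MMF mouse 14 (0.344) or multi-target mouse 39 (0.0825), the podocyte call without MMF mouse 1 (0.463) or multi-target mouse 6 (0.202), and the interferon call against FK506 without multi-target mouse 39 (0.796). The macrophage and T cell calls against prednisone ended without prednisone mouse 23 (0.214 and 0.0682), and their medians were -1.13 and -0.89 without mouse 29. The T cell median was -0.83 without multi-target mouse 39. Against MMF the glucocorticoid median was -1.03 without MMF mouse 1 and -0.78 without multi-target mouse 18, and the podocyte median 0.29 without MMF mouse 14. Against FK506 the interferon median was 0.22 without FK506 mouse 3 and 0.63 without multi-target mouse 6. Without FK506 mouse 12 the adrenal median against FK506 was 0.08 (adjusted p = 0.7). Array weights gave 6935 genes against MMF, 2049 against FK506 and 1 against prednisone. Without prednisone mouse 23 camera called 4 lists against prednisone in place of 16.

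The multi-target effect was also set against the sum of the 3 single-drug effects. The contrast lay above 0 where each single drug lay below it. Where all arms lower a list by a like amount, subtracting 3 effects from 1 gives such a value by itself. The sign alone therefore does not show how drugs combine, and the labels do not say that the arm held these 3 drugs. Macrophage markers were above 0 in 22 of 22 members (1 higher adjusted over the list alone), with Mrc1 at 1.57, interferon-stimulated genes in 25 of 25 (2 higher adjusted over the list alone), with Ifi27l2a at 2.41, and antigen presentation genes in 17 of 17 (0 adjusted over the list alone), with Ciita at 3.17; adjusted p = 0.522 with an estimated correlation for each. The interferon median of 2.43 was 1.30 without vehicle mouse 36. Rcan1 stood at 2.75 ± 0.71 and Fkbp5 at -2.58 ± 0.95, both with a limma adjusted p of 0.327. Limma called 0 genes, with 2286 under the threshold unadjusted and 0 by voom, and camera 19 lists. The contrast adds the vehicle mean 2 times, so high vehicle libraries raise it, and doses are unknown. The count was 1397 without MMF mouse 1 and 4357 with array weights.

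Treated kidneys were then compared with healthy ones, which share no library with the vehicle group. Saa3 and Fpr2 stayed above the healthy level in every arm, with Saa3 at 4.41 ± 0.52 in MMF, 5.98 ± 0.52 in FK506, 7.04 ± 0.52 in prednisone and 6.37 ± 0.52 in multi-target mice (limma adjusted p = 0.000291, 3.63e-05, 4.59e-06 and 2.59e-05). Ubd was higher by 3.98, 3.78, 5.92 and 3.97 in the same order. Prlr was lower by log2 values of -4.19, -3.02, -3.96 and -3.25. Kap, a kidney protein under androgen control, was lower in MMF (-6.35 ± 1.88, limma adjusted p = 0.0358) and prednisone mice (-5.75 ± 1.88, 0.0484), and stood at -3.94 ± 1.88 in FK506 (0.205) and -4.14 ± 1.88 in multi-target mice (0.186). Its log2 values were 15.03, 16.92 and 14.12 in vehicle mice 7, 17 and 36, and 17.81, 17.76 and 17.87 in healthy mice. On average every treated arm thus lay farther below healthy than vehicle did, though single mice overlapped, with FK506 mouse 24 at 17.42. Between arms, Kap stood at 2.21 for multi-target against MMF and 1.60 against prednisone (limma adjusted p = 0.742 and 0.993), and FK506 was not tested against these 2 arms. In MMF mice 2395 genes differed from healthy, in FK506 mice 1093, in prednisone mice 2509 and in multi-target mice 1049. Without healthy mice 1, 2 and 3 in turn the counts were 513, 665 and 625 for MMF, 266, 286 and 354 for FK506, 1114, 1168 and 1281 for prednisone, and 223, 303 and 344 for multi-target. The MMF count was 5802 without MMF mouse 1, 487 without mouse 14 and 933 without mouse 27. The FK506 count was 363 without FK506 mouse 3 and 239 without mouse 12, the prednisone count 1036 without prednisone mouse 23 and 1197 without mouse 35, and the multi-target count 321 without multi-target mouse 6 and 320 without mouse 18. Quantile normalization moved the share of higher calls from 60% to 47%, 78.8% to 53.4%, 80.3% to 46.7% and 76.4% to 50.5%.

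Movement along the disease difference was expressed as a reversal slope over all genes. The slope was -0.436 ± 0.170 (SD, n = 3 mice) for MMF, -0.423 ± 0.065 for FK506, -0.170 ± 0.293 for prednisone and -0.414 ± 0.032 for multi-target. This SD is between treated mice with the vehicle mean held fixed, so it leaves out the spread of the vehicle mice. Vehicle mice 7, 17 and 36 themselves stood at -0.258, -0.09 and 0.348. Of the 3369 disease genes, 85.3% had an estimate toward healthy with MMF, 90.8% with FK506, 80.9% with prednisone and 90.2% with multi-target. In 100 simulations of unchanged groups the slope had a median of -0.0148 and a central 95% range from -0.309 to 0.260, and the share had a median of 68.2% with a range from 25.1% to 91.1%. A slope as low as the observed one arose in 0 of 100 simulations for MMF, FK506 and multi-target and in 11 for prednisone. A share as high arose in 17 for MMF, 5 for FK506, 28 for prednisone and 7 for multi-target. Residuals were pooled over the 15 MRL/lpr libraries. A wider spread among vehicle mice is therefore not reproduced, and these counts may be too low. The disease genes with a rise had a median log2 difference of 0.89 in vehicle mice, and of 0.46, 0.50, 0.75 and 0.52 in the same 4 arms against healthy. Those with a fall had a median of -0.71 in vehicle mice, and of -0.49, -0.39, -0.53 and -0.425 in these arms. The genes were called in the same vehicle libraries, so an unchanged group would also give smaller medians. The size of that drop was not simulated. Without vehicle mouse 36 the slopes were -0.290 for MMF, -0.255 for FK506, -0.009 for prednisone and -0.255 for multi-target. Each of these lay inside the simulated range. That range was simulated with all 3 vehicle libraries, mouse 36 among them, and none was simulated for this setting. The prednisone slope was -0.287 without vehicle mouse 7, -0.327 without prednisone mouse 23 and -0.036 without prednisone mouse 29.

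**Figure D3:**
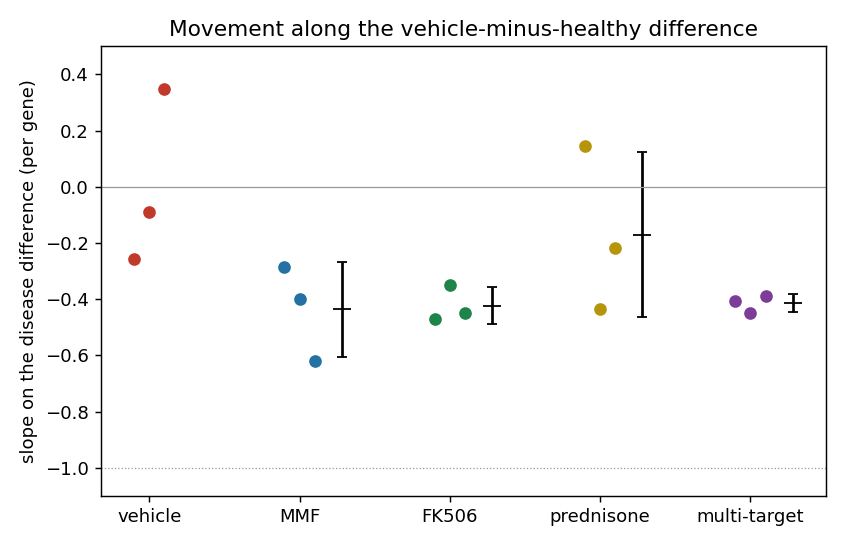
Slope of each mouse (points) and of each treated group (bars, with the SD between 3 mice) on the vehicle-minus-healthy difference across genes, on the y axis, for the 5 MRL/lpr groups on the x axis; the solid line is 0, the vehicle mean, and the dotted line -1, the healthy level. Group slopes were -0.436 for MMF, -0.423 for FK506, -0.170 for prednisone and -0.414 for multi-target. The bars leave out the spread of the vehicle mice.

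The drug effects were compared with one another across genes, which are not independent replicates. The correlation was highest for FK506 and multi-target (0.926) and lowest for MMF and prednisone (0.830). Unchanged groups sharing the vehicle libraries gave a median correlation of 0.568 with a range from -0.356 to 0.928. Covariance ran from 0.110 (prednisone and multi-target) to 0.227 (MMF and FK506), against a simulated median of 0.0338 with a range up to 0.154. The covariance expected from sharing the vehicle libraries was 0.0404. It was computed from residual variance pooled over all 6 groups, so it is too low where vehicle mice vary more than the others. FK506 and multi-target shared 1133 genes lower at an unadjusted p, where independent lists would share 172.7 and unchanged groups a median of 9 with a range up to 880. They shared 653 genes higher, against 70.9 for independent lists and a simulated median of 8 with a range up to 636. With 3 vehicle libraries the controls could not be split, so part of the excess may come from them. The excess covariance of this pair was 0.152, with 0.0592 without vehicle mouse 36 and 0.258 without vehicle mouse 7.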

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

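Whole-read voom and leaving out both libraries with other-tissue transcripts (vehicle mouse 17 and FK506 mouse 12) were chosen after the data were seen; the other alternatives were fixed before the data were examined. Unless stated otherwise, the cause of a difference was not tested. Array weights did not reach their convergence tolerance and gave multi-target mouse 6 a weight of 26.6, vehicle mouse 36 0.168 and MMF mouse 1 0.0955, so their counts are of doubtful use. The planned pseudocount and negative binomial alternatives, meant for linear values or raw counts, were not run on these log2 values. When 1 mouse is left out, the remaining 2 of its group are assumed to vary like the other groups. Counts without the lowest 25% of genes are over the remaining genes, and voom counts over the 11164 whole-read genes. Such counts can be lower because fewer genes were tested.

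The disease count of 3369 was 2226 without the lowest 25% of genes and 5519 with array weights, and 1490 to 4023 with 1 library left out. The MMF count of 238 was 28 without the lowest 25%, 6753 with array weights, and 0 with only both groups fitted, with quantile normalization, with voom and without both doubtful libraries; it ran from 0 to 5538 with 1 library left out. Array weights gave 2326 genes for FK506, 2785 for multi-target, 6935, 2049 and 1 for multi-target against MMF, FK506 and prednisone, and 4357 for the departure from the sum. With 1 library left out these ran from 0 to 1 for FK506, 0 to 38 for multi-target, 0 to 2521 against MMF and 0 to 1397 for the departure; against MMF, leaving out the lowest 25% gave 1.

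Against healthy, MMF gave 1459 with only both groups fitted, 8889 with array weights and 1385 with voom, and 487 to 5802 with 1 library left out. FK506 gave 606 without the lowest 25%, 3673 with both groups only, 710 with quantile normalization, 8559 with array weights, 606 with voom and 213 without both doubtful libraries, and 239 to 1162 with 1 left out. Prednisone gave 4111 with both groups only and 5697 with array weights, and 1036 to 2969. Multi-target gave 623, 3238, 675, 9926 and 610 in the order lowest 25% left out, both groups only, quantile normalization, array weights and voom, and 223 to 1293. The FK506 slope was -0.298 with array weights and -0.498 without both doubtful libraries, and -0.523 to -0.255 with 1 left out; the multi-target slope was -0.334 with array weights, and -0.515 to -0.255. The excess covariance of FK506 and multi-target ran from 0.0592 to 0.258.

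With an estimated correlation camera called 0 lists in each of the 13 comparisons, the 4 treated-against-healthy ones included. Fry called 4 for MMF and 0 for the other 7 drug comparisons. Without the lowest 25% 15 lists were called in disease and 6 for multi-target against FK506, which array weights also took to 6. Lists left with under 5 members were not tested without the lowest 25%, so those counts are over fewer lists. Over the 9 comparisons other than treated against healthy, 117 called list results kept their call there and 5 lost it. Multi-target against MMF had 8 lists with both groups only, 6 with quantile normalization and 1 to 5 with 1 library left out. The ranges were 15 to 24 for prednisone, 6 to 13 for multi-target against FK506 and 4 to 18 against prednisone.

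Of 155 called list results, 19 turned direction somewhere, in 31 values. With array weights the medians were -0.10 for proximal tubule in FK506, -0.06 in prednisone and 0.57 in the departure, -0.013 and 0.03 for oxidative phosphorylation in prednisone and the departure, and -0.05 for collecting duct in multi-target against FK506. Without both doubtful libraries they were 0.24 and 0.18 for adipocyte markers in prednisone and multi-target, 0.72 and -0.048 for urothelial markers, and 0.22, 0 and 0.084 for neutrophil, oxidative phosphorylation and adrenal lists in multi-target against FK506. With 1 library left out, prednisone medians ran from -1.08 to 0.25 for tubular injury, -0.094 to 0.54 for proximal tubule, 0.044 to 0.60 for loop of Henle, -0.061 to 0.26 for oxidative phosphorylation, -2.14 to 0.24 for adipocyte and -1.44 to 0.72 for urothelial markers. Multi-target medians ran from -3.19 to 0.18 for adipocyte and -2.45 to -0.048 for urothelial markers. Against FK506 they ran from -0.89 to 0.22 for neutrophil, -0.006 to 0.11 for oxidative phosphorylation and -2.47 to 0.084 for adrenal lists. Against prednisone they ran from -0.89 to 0.017 for injury, -0.79 to -0.04 for matrix, -0.68 to 0.005 for cell cycle and -0.31 to -0.045 for actin. In the departure they ran from -1.03 to 0.30 for proximal tubule and -0.60 to 0.043 for oxidative phosphorylation. Direction here is that of camera, which compares a list with all other genes, so a median can keep its sign. Depth was not tested against these turns; 0.151% of values were under 10 reads.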

Other observations

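Chosen after the result was seen were the tests of component 2 against depth, glucocorticoid-induced genes and male-biased kidney genes. So were the comparison with female-biased kidney genes and the tests of tissue transcripts in single libraries. Mice of the same group differed in Kap. This proximal tubule gene under androgen control was between 17.8 and 17.9 on the log2 scale in the 3 healthy mice, and within MMF it was at 15.87 in mouse 1, 10.71 in mouse 14 and 7.79 in mouse 27. Within prednisone it was at 14.26, 12.98 and 8.95 in mice 23, 29 and 35.

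A set of 300 genes lay apart from healthy by a like amount, within 0.5 on the log2 scale, in all 5 MRL/lpr groups, with 202 higher and 98 lower. Each had an adjusted p under 0.05 in all 5 comparisons. These comparisons subtract the same 3 healthy libraries, so any deviation of the healthy mean appears alike in each. The number of genes this alone would give was not computed. Leaving out numbered gene models, the largest were Ezh1 (mean 2.37), Slc22a26 (-2.28), Cp (2.16) and Sult2a4 (-2.05). Sequence carried along with the lpr allele would place them near Fas on chromosome 19 (34290666 to 34327772). Of the 285 with a location 5, or 1.75% (0.572% to 4.05%), lay within 10 Mb, Fas among them, against 0.906% of other genes, so this was not the source of most of the set. For the near genes it stays open (odds ratio 1.95, one-sided Fisher's exact p = 0.124). Separate handling of the healthy libraries could also give such a set of 300 genes and cannot be told apart from strain and disease, since only those libraries are wild type.

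Component 2, with 28.8% of the variance, spread the mice within every MRL/lpr group, and was set against 4 measures as deviations from the group means over 15 libraries. Depth gave r = 0.048 (exact permutation p = 0.868, adjusted 0.868; rho = 0.107, p = 0.759; r = 0.034 without the 2 libraries farthest out), far from a relation that would make it the source. Collecting duct markers gave r = 0.521 (exact permutation p = 0.0563, adjusted 0.0751, rho = 0.507 with p = 0.0567, and r = 0.555 without 2). The prediction for more medulla in a piece was a negative r, so the sign was opposite to it. That prediction took component 2 to fall with more medulla, which was not checked. Uneven sampling of cortex and medulla is therefore not excluded. Glucocorticoid-induced genes gave r = -0.828 (exact permutation p = 0.0072, adjusted 0.0144; rho = -0.825, p = 0.00669; -0.732 without 2), and the 8 male-biased kidney genes, Kap among them, gave r = 0.958 (exact permutation p = 0.0018, adjusted 0.0072; rho = 0.936, p = 0.00296; 0.944 without 2). Glucocorticoid exposure or stress of a mouse and a difference in androgen level between mice were candidate explanations, found and tested on the same libraries. These relations do not separate them, and other candidates were not tested. Proximal tubule markers were not set against component 2. In vehicle, MMF, FK506 and multi-target the mouse highest on component 2 was also highest in these markers (-0.635, -0.535, -0.42 and -0.457 against healthy). In prednisone mouse 23 was highest on component 2 (7.85, with mouse 29 at 7.23) and mouse 29 highest in the markers (-0.527). Lower androgen was taken to lower male-biased and raise female-biased genes, an expectation that was not checked in these mice. Yet in each MRL/lpr group the mouse highest in the male-biased list was also highest in the female-biased list. Female-biased means against healthy ran from -1.138 to -0.25 in FK506 mice and from -1.53 to -1.035 in MMF mice. In MMF and FK506 the order of the other mice differed between the lists. This went against the expectation. A level shared by both lists of kidney genes could hide opposite changes, so the comparison does not decide on androgen level.

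Vehicle mouse 17 and FK506 mouse 12 held transcripts of other tissues. In vehicle mouse 17, 75% of 8 further adipocyte markers were at their highest of all libraries (median 5.20 above the others; Cfd 10.97 above) and 80% of 5 further urothelial markers (median 3.41; Upk1b 4.43). In FK506 mouse 12, 85.7% of 7 further adrenal markers were at their highest (median 4.26; Hsd3b1 7.44). Fat, urothelium of the renal pelvis and adrenal tissue in the pieces are candidate sources. No biological explanation of these transcripts, such as a change in the kidney itself, was tested.

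With 3 mice against 3 there are 10 splits, too few for a share under 0.05. Counts of splits include the real one. In disease 1 split, the real one, gave as many genes (3369; highest other 0). For MMF 3 did (238; highest other 1686), and a split calling several times the real count points to a structure of the samples. For FK506, prednisone and multi-target the real count was 0, which 10 of 10 must reach, with highest others of 0, 345 and 11. For multi-target against MMF, FK506 and prednisone it was 10 of 10, with highest others of 2847, 0 and 0, the first again pointing to a structure of the samples. Against healthy, only the real split (1 of 10) gave as many for MMF (2395; highest other 1), FK506 (1093; 0), prednisone (2509; 0) and multi-target (1049; 0). A slope as low came only from the real split (1 of 10) for MMF (-0.436; other -0.433), FK506 (-0.423; other -0.32) and multi-target (-0.414; other -0.348), and from 4 splits for prednisone (-0.17; other -0.386). For the departure from the sum the real count was 0 as well, which each of the 100 drawn regroupings must reach, so this says nothing about chance; the highest gave 5106, which points to a structure of the samples.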
